A study of Mus musculus with 4 samples.

How the data were processed

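CTCF ChIP-seq was done on frozen left cerebral cortex of adult female B6CASTF1/J mice, in 4 libraries with a size range of 200 to 600 bp per the labels. The libraries were grouped by pool as the labels give it, pool I and pool J, with 2 technical replicate libraries each. Both libraries of a pool share 1 alignment file per the notes deposited with the lists, so values per library are not used here. Libraries of different pools share technical replicate numbers only as names.

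The authors deposited 8 peak lists on mm10, of which 4 were thresholded by irreproducible discovery rate (IDR) and 4 were the ranked lists before that threshold. The IDR estimates, from 2 inputs, the share of irreproducible peaks among those ranked at least as high. Per the deposited notes, a pair of each kind came from pool I, from pool J, from both pools as replicates and from the pooled reads. Which input of the list of both pools was which pool was checked by matching intervals: 84.5% of the first inputs were identical to a ranked pool I peak, 61.8% of the second to a ranked pool J peak, and 0% crosswise. The score of each deposited peak is a scaled IDR, the whole part of minus 125 times log2 of the IDR up to 1000. That relation was tested on the ranked lists and held within 1 score unit for 100% of peaks. The lowest score in every thresholded list was 540, which corresponds to an IDR of 0.05. The ranked lists deposited by the authors also give the IDR as −log10. The signal value deposited by the authors for each peak is in the peak caller's own unit, which was not stated. Scores and signal values are thus the authors' own peak values. The aligner, the peak caller, their versions and the identity of the control are not given in the sources used here. Both the ranked and the thresholded lists hold a summit per peak, and a peak interval with several summits is listed once per summit, so the 44672 conservative peaks form 44263 separate intervals. The ranked lists gave the signal value per pool and the peaks below threshold. Their peaks on scaffolds and the mitochondrial chromosome entered only the signal correlation over all ranked peaks and the closing section.

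The reference was GRCm38.p6, whose chromosome lengths are those of mm10, with the GENCODE M21 basic annotation (21938 protein-coding and 10155 lncRNA genes on chromosomes 1 to 19, X and Y). Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The read depth is unknown, as the lists carry no counts, so no interval that needs it is given. Binomial intervals are exact (Clopper-Pearson, 95%) and cover counting of peaks only.

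Lists of the pools were compared by overlap of at least 1 bp, with 1000 circular shifts within chromosomes. The self-consistency ratio was the larger over the smaller pool list. The motif was learned from the strongest 1000 conservative peaks on odd-numbered autosomes, seeded by a degenerate CTCF core sequence, with the score threshold that 1% of flanking windows there passed. Shares were measured on the even-numbered autosomes and X. Orientation was tested on all chromosomes with 10000 random reassignments of strand. Summits were placed in order of priority as promoter (1000 bp from a TSS), 5' UTR, coding exon, 3' UTR, noncoding exon, intron or intergenic, against 100 random sets of non-N positions matched by chromosome. The noncoding exon class was added to the planned ones, since lncRNA genes have no coding sequence.

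The 18 gene lists were fixed before the data were examined: imprinted genes, X inactivation centre and escape genes, clustered protocadherins, Hox genes, olfactory receptors, ribosomal proteins, CTCF and cohesin factors, activity-regulated genes, synaptic adhesion and scaffold genes, markers of excitatory and inhibitory neurons, astrocytes, oligodendrocyte lineage, microglia and endothelium, and liver, skeletal muscle and erythroid genes. CTCF binding is not expression, so the marker lists are gene groups only. Of the list of CTCF and cohesin factors 19 of 20 symbols were in the annotation, and of each other list all were. Promoter lists were tested by two-sided Fisher's exact test, with Benjamini-Hochberg adjustment, and beside 10000 random lists matched on biotype and length decile. Lists over whole genes with 10 kb upstream were called by such matched lists alone (two-sided permutation test). Fisher's exact test was also run on them and is given beside those calls.

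Genes were named by a rule fixed beforehand. Imprinted and X inactivation genes were named for up to 6 with the strongest peak in the gene or 10 kb upstream and up to 3 with none, and Ctcf was always named. Every other list gave the 3 members with the strongest promoter peak and the alphabetically first 2 without. The 10 strongest peaks, the 5 strongest unshared peaks per pool and the 3 protein-coding genes nearest the middle of each of the 10 densest 100 kb windows (50 kb steps) were also named, passing over clone symbols. A few items that the rule selects are not named here. H19, Firre as the gene in the densest window, and the location of the Peg13 promoter fall outside that rule and were chosen after the values were seen.

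Steps were tested on simulated data. Lists made to share 50% of peaks gave 50.8% overlap over 44672 peaks. An exact CTCF core planted in 60.0% of 4000 random windows was found in 60.7%, with 100% of strands right. That scan used the degenerate core sequence that seeds the motif. The learned motif and its weaker matches were not tested on simulated data. Random strands gave 25.3% convergent pairs over 30594 pairs. Gene lists of 20 with no effect passed 0.05 by Fisher's exact test in 2.5% of 200 draws, and lists with 80% against 30% of genes in 99%. Those simulated genes were independent of each other. Genes that share a peak and the length-matched permutation test were not tested on simulated data.

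Alternatives fixed beforehand were an IDR of at most 0.01 (score of 830), the optimal list, each pool's own list, other overlap rules, motif windows and thresholds, pair distances, promoter windows, upstream reaches, chromosome lengths and window sizes. Added after the data were seen were the strongest peaks by signal value without the IDR threshold and chromosome length outside repeats.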

Results

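CTCF, the zinc finger protein that binds insulators and the anchors of chromatin loops, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the left cerebral cortex of adult female mice aged 2 months. The animals were B6CASTF1/J, the first-generation cross of C57BL/6J and CAST/EiJ by strain name. The series held 4 libraries, made as 2 technical replicates from each of 2 pools, and each pool combined 4 cortex biosamples. Pool I was the first biological replicate and pool J the second. There was 1 condition and 1 antibody, so the comparisons are between the pools, between sites and sequence, and between groups of genes or regions. The 8 peak lists analysed were made after both libraries of a pool had been merged, so no value per library is given, the read depth is unknown, and no p-value treats the pools as replicates of a group. Signal values are the peak caller's own, in a unit that was not stated. They were used to rank peaks, to compare groups of peaks within a list and, as log2 values, to compare the pools. All coordinates are on mm10 and 1-based.

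CTCF occupied many short sites across the cortex genome. The list supported by both pools, called the conservative list here, held 44672 peaks with a median width of 309 bp, which covered 13.2 Mb or 0.497% of the non-N genome. The list made from the pooled reads of both pools, called the optimal list here, held 50827 peaks with a median width of 319 bp. Pool I alone gave 82131 peaks and pool J alone 52658, with median widths of 396 and 350 bp. Each of these medians is also the most frequent width, shared by 41.5% of pool I and 53.2% of pool J peaks. They are therefore not read as a difference in the size of sites between the pools. The ratio of the larger to the smaller pool list was 1.56, and the ratio of the optimal to the conservative list was 1.14. No list held a peak on chromosome Y.

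The first comparison asked how far the sites of one pool of mice were found in the other. Nearly every pool J site was also a pool I site, whereas pool I held many further sites, most of them among its weaker peaks. Of the pool J peaks, 97.5% (51345 of 52658; exact 95% binomial interval 97.4 to 97.6%) overlapped a pool I peak by at least 1 bp. Of the pool I peaks, 63.1% (51836 of 82131; 62.8 to 63.4%) overlapped a pool J peak. Circular shifts of a list within its chromosomes gave means of 2.02% and 1.31%, and the one-sided permutation p was 0.001 in both directions, the smallest that 1000 shifts can give. By quintile of signal value, 99.99% of the strongest pool I peaks were shared, 76.3% of those in the middle quintile and 11.6% of the weakest. The weakest quintile of pool J peaks was still shared at 88.2%. Taking the strongest 52658 peaks from each list, 88.8% of pool I and 89.7% of pool J peaks were shared.

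**Figure D1:**
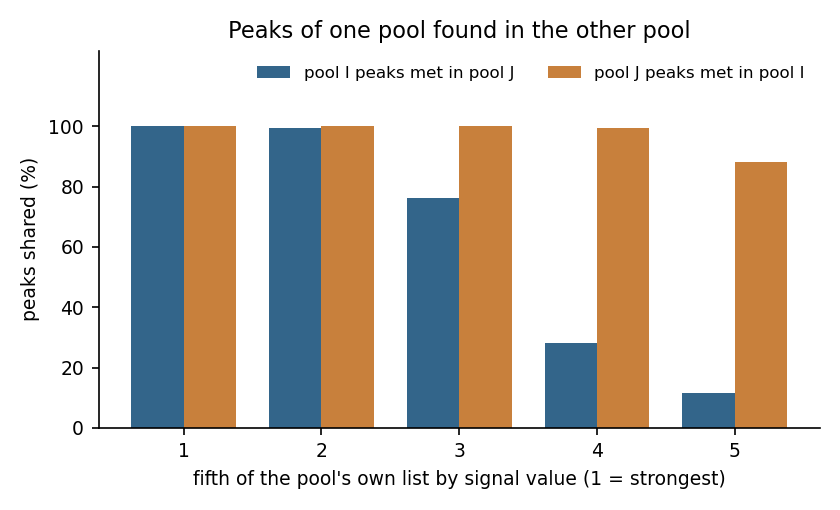
Share of each pool's own peaks (vertical axis, percent) that overlap a peak of the other pool's list by at least 1 bp, by quintile of signal value (horizontal axis, 1 is the strongest). Bars for pool I fall from 99.99% to 11.6%, and bars for pool J stay at 88.2% or above.

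Signal values of the pools rose and fell together across sites, most closely in the conservative list, which the IDR selects for like ranks in both pools. There Spearman's rho between the signal values of the pools was 0.969 and Pearson's r of the log2 values was 0.957, both across 44672 peaks, which are not independent replicates. The median log2 ratio of pool I to pool J signal was 1.09 with an SD of 0.39 over peaks, and 210 peaks (0.470%) lay more than 2-fold from that median. With unit and read depth unknown, the median ratio is not read as stronger binding in pool I. Over all 133567 ranked peaks, which the IDR threshold did not select, rho was 0.875 and 16.4% lay more than 2-fold from their median log2 ratio.

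The strongest pool I peak without a pool J counterpart lay on chromosome 13, 110368506 to 110369089, 11686 bp from the nearest transcription start site (TSS), that of Gapt. The next lay on chromosome 15, 72809933 to 72810548, at the promoter of Peg13, an imprinted non-coding RNA transcribed from within an intron of Trappc9. Others of the 5 strongest lay in a coding exon of Cabp4 and at the promoter of Lrrk1. All 5 overlapped a peak of the conservative list and a peak of pool J's ranked list below its threshold. The 5 strongest pool J peaks without a pool I counterpart lay in an intron of Iffo2 (chromosome 4, 139611692 to 139612045), near Ebf2, near Rrp1, within the span of Gucd1 and in the 3' UTR of Cerk. Each of these overlapped a pool I ranked peak below the threshold, and 3 of the 5 were in the conservative list.

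The second comparison asked how often a CTCF motif lay under the peaks. Most summits lay close to the motif, and strong peaks held it more often than weak ones. A 20 bp motif learned from the strongest peaks of the odd-numbered autosomes read GTGGCCACCAGGGGGCGCTA by the most frequent base at each position. On the even-numbered autosomes and X, 65.5% of 20861 conservative summits (13673; exact 95% interval 64.9 to 66.2%) had a match within 50 bp, against 0.952% of the windows 1000 bp to each side, a 68.9-fold difference. The odds ratio was 198, and the two-sided Fisher's exact p lay below the smallest number the software can represent. The share fell from 84.4% in the strongest decile of peaks to 48.3% in the weakest. Over all chromosomes the median distance from motif centre to summit was 6 bp, and 92.8% of 29214 matches lay within 20 bp. The share was 63.1% in the optimal list, 60.6% in pool J's list and 53.6% in pool I's list. Pool I peaks that no pool J peak overlapped held a motif in 39.5% of cases, against 0.832% in their flanks, and those shared with pool J in 61.9%. The share depends on how strict a match is, and a threshold that 0.1% of flanking windows passed left 13.3%.

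**Figure D2:**
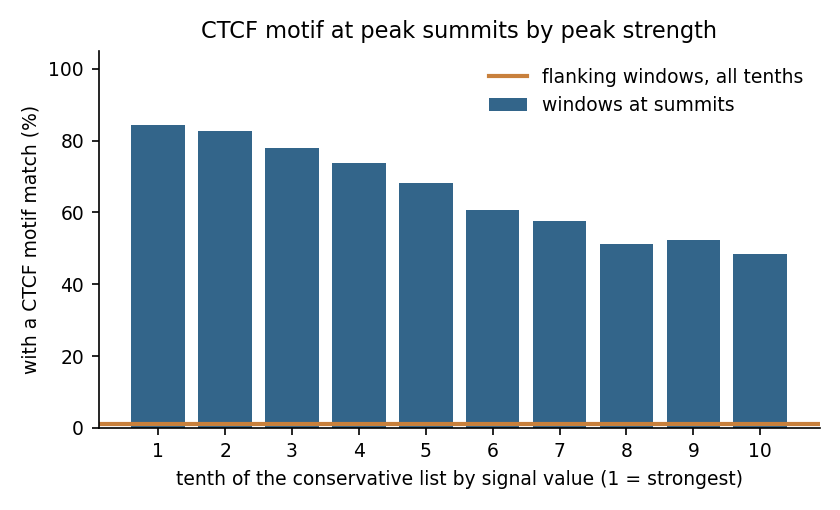
Share of conservative summits with a CTCF motif match within 50 bp (vertical axis, percent) by decile of signal value (horizontal axis, 1 is the strongest), on even-numbered autosomes and X. Bars fall from 84.4% to 48.3%, and the line marks the 0.952% of flanking windows with a match.

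The strongest conservative peak lay on chromosome 15, 102065632 to 102066099, in intergenic sequence 7914 bp from the TSS of Eif4b, a translation initiation factor gene. Others of the 10 strongest lay near Epm2aip1, Ier5 and Ddr1, in an intron of Atxn7, near Atp23, at the promoter of Cep120, near Chrm3 and in the 3' UTR of Ptges2. Of these 10 peaks, 6 were intergenic. The peak in Atxn7 (chromosome 14, 14098519 to 14099025) had no motif match within 50 bp. In the ranked list of both pools 13 peaks had a higher signal value than the strongest of these and were not in the conservative list.

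The third comparison concerned the order of motifs along the chromosome, since motifs that face each other are the arrangement usually found at loop anchors. Neighbouring sites faced each other slightly more often than random strands would, and this rested on distant neighbours. Of 22279 neighbouring pairs 10 kb to 1 Mb apart, 26.0% were convergent, 23.4% divergent and 50.6% on the same strand. Random reassignment of strands gave 24.2 to 25.7% convergent pairs over 10000 draws ( two-sided permutation p = 0.0002, the smallest they can give). In distance bins added after the tests had been fixed, convergent pairs rose from 17.5% below 10 kb to 21.0% at 10 to 50 kb, 29.6% at 50 to 200 kb and 35.2% at 200 kb to 1 Mb. Divergent pairs went from 27.1% and 27.6% in the nearer bins to 20.4% and 15.6% in the farther ones. The farthest bin exceeded the nearest by 17.7 percentage points in convergent pairs, against -3.10 to 3.60 in 10000 strand shuffles (two-sided permutation p = 0.0002, the smallest they can give). With the stricter motif threshold of 0.1%, the convergent share over all pairs was 24.7% and no longer differed from random strands (permutation p = 0.45).

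**Figure D3:**
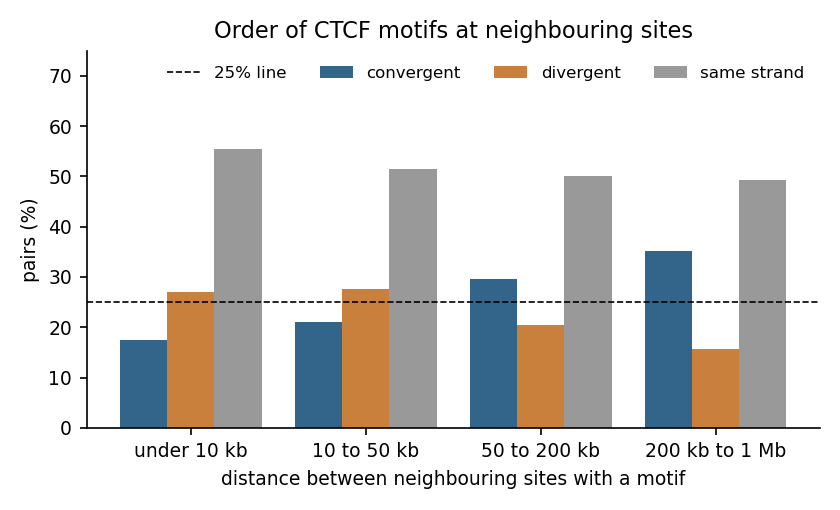
Share of neighbouring motif-bearing sites in convergent, divergent and same-strand order (vertical axis, percent) by the distance between them (horizontal axis). Convergent pairs rise from 17.5% below 10 kb to 35.2% at 200 kb to 1 Mb, and the dashed line marks 25%.

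The fourth comparison placed the summits in the gene annotation. CTCF sites were concentrated at promoters, though most lay in introns and between genes. Summits within 1000 bp of a TSS made up 12.2% (5465) of the conservative list, 4.24 times the 2.88% of random positions on the same chromosomes. Coding exons held 1.99% against 1.24%, 3' UTRs 1.87% against 1.27% and introns 43.8% against 41.0%. Intergenic sequence held 39.4% against 53.2%, and was the only category of the 7 with fewer summits than random positions. For each category the two-sided permutation p was 0.02, the smallest that 100 random sets can give. With a promoter window of 5000 bp introns held 35.8% and no longer differed from random positions (permutation p = 0.85). On the even-numbered autosomes and X, 35.7% of promoter summits held a motif, against 68.5% in introns and 71.3% in intergenic sequence. Over all chromosomes the median signal value of promoter summits was 245, against 246 in introns and 302 in intergenic sequence.

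The fifth comparison was between chromosomes, and chromosome X stood apart. It held 7.49 peaks per Mb of non-N sequence, fewer than every autosome. The autosomes had a median of 18.5, from 13.8 on chromosome 3 up to the densest, chromosome 11. X thus had 0.404 times the autosome median (exact 95% binomial interval of the X count 0.382 to 0.427). Among the autosomes and X it also had the second lowest density of protein-coding genes, at 5.80 per Mb, above chromosome 12 at 5.50, a chromosome with 14.8 peaks per Mb. The median signal value on X, 240, was the lowest of the 20 chromosomes in the conservative list, while in pool I's list X had the highest median and in pool J's it ranked 18. Counted per Mb of sequence outside repeats, an alternative chosen after the data were seen, X had 0.514 times the autosome median and stayed the lowest. Only the length left out repeats there, and peaks inside repeats were still counted.

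**Figure D4:**
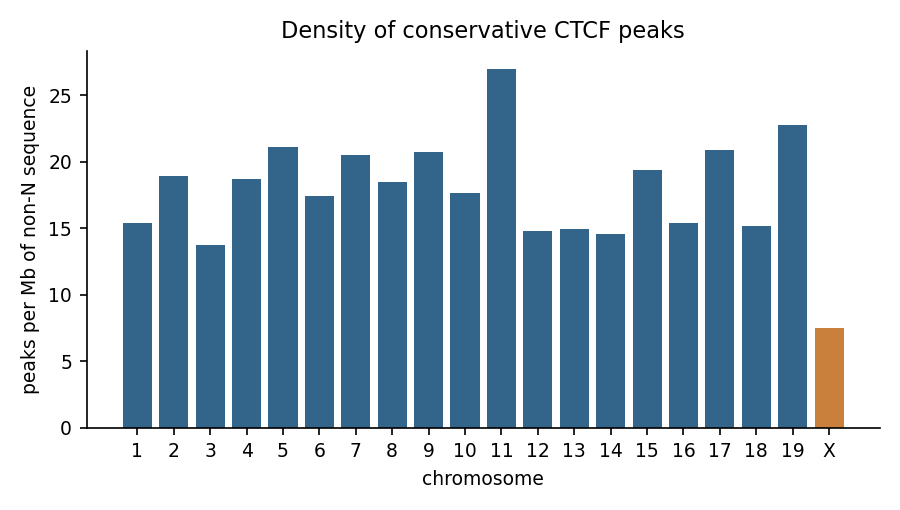
Conservative CTCF peaks per Mb of non-N sequence (vertical axis) for each autosome and X (horizontal axis). X lies at 7.49, below the autosome minimum of 13.8.

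The sixth comparison asked which groups of genes carry CTCF at their promoters. Clustered protocadherins, the cell surface proteins that give neurons their individual identity, had a promoter peak far more often than other genes, and olfactory receptors almost never did. Of all protein-coding genes 20.8% (4556 of 21938) had a summit within 1000 bp of a TSS, and of lncRNA genes 10.6% (1081 of 10155). Of the 18 lists fixed beforehand, 4 passed an adjusted p of 0.05 by Fisher's exact test with Benjamini-Hochberg adjustment over the lists. Genes of a cluster lie side by side and are not independent.

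Among the clustered protocadherins 41 of 57 (71.9%; adjusted Fisher's exact p = 1.3e-15) had a promoter peak, each a different peak, against 14.0 in random lists matched on gene length. The strongest lay at Pcdhac1 (chromosome 18, 37089754 to 37090146; higher than 97.6% of conservative peaks), then at Pcdhga12 and Pcdhgc3. Pcdha1 and Pcdha3 were among those without. Of the olfactory receptors 8 of 1093 had one (0.732%; adjusted Fisher's exact p = 1.3e-97), against 173 in matched lists. The exceptions were led by Olfr557 and Olfr556, which are neighbours on chromosome 7, and Olfr1499 on chromosome 19. Olfr1 and Olfr10 had none. Ribosomal protein genes, needed in every cell, had one in 33 of 80 (41.3%; adjusted Fisher's exact p = 0.00023), against 11.5 in matched lists. Rps3a1 and Rpl36 were among the 3 with the strongest promoter peaks, and Rpl10l and Rpl12 had none.

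Genes for CTCF, cohesin and their partners had a promoter peak in 10 of 19 (52.6%; adjusted Fisher's exact p = 0.0096), against 4.69 in length-matched lists (adjusted permutation p = 0.073). Stag1 and Pds5b, which encode cohesin subunits or regulators, and Esco1, a cohesin acetyltransferase, held the strongest peaks. Ctcf itself had a promoter summit on chromosome 8 at 105636839, stronger than 69.7% of conservative peaks and without a motif match, and Cdca5 and Ctcfl had none. This call was lost in pool J's list (adjusted p = 0.061) and with promoter windows of 500 bp (0.092) or 5000 bp (0.078), all by Fisher's exact test.

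The other 14 lists did not pass. Activity-regulated genes, which neurons switch on after firing, had a promoter peak in 8 of 20 (adjusted Fisher's exact p = 0.18), strongest at Egr1, Dusp1 and Bdnf, with none at Arc or Btg2. Synaptic adhesion and scaffold genes had one in 9 of 27 (0.37), strongest at Nrxn2, Nlgn1 and Grin2a, with none at Cntnap2 or Ctnnd2. X inactivation and escape genes had one in 5 of 15, imprinted genes in 10 of 41, and Hox genes, silent in most of the forebrain, in 5 of 39, led by Hoxc5, Hoxa10 and Hoxb5, with none at Hoxa11. Excitatory neuron markers had one in 4 of 17 (Cux2, Foxp2 and Cux1 the strongest, none at Camk2a or Emx1). Inhibitory neuron markers had one in 3 of 17, at Calb2, Gad1 and Pvalb, with none at Adarb2 or Dlx1. Oligodendrocyte lineage markers had one in 3 of 14, at Myrf, Pdgfra and Olig2, with none at Cldn11 or Cnp. Single members of the astrocyte (Slc1a2, 1 of 12), microglia (C1qa, 1 of 13), endothelial (Egfl7, 1 of 11) and erythroid (1 of 10) lists had one, and Aldh1l1, Aldoc, Aif1, C1qb, Abcb1a, Cdh5, Alas2 and Epb42 did not. The Slc1a2 promoter peak was weak, at the 4.10 percentile of conservative peaks, and had no motif match. With an IDR of at most 0.01, 0 of 12 astrocyte markers had a promoter peak. Skeletal muscle genes had one in 3 of 12, at Mylpf, Tnnt3 and Myod1, with none at Acta1 or Actn3, and liver genes in 0 of 12, Ahsg and Alb among them. The 5000 bp window brought imprinted (adjusted Fisher's exact p = 0.00083), activity-regulated (0.00013), synaptic (0.014) and skeletal muscle genes (0.038) past the threshold. Pool I's list brought synaptic (0.0044), Hox (0.031, fewer) and liver genes (0.015, fewer) past it.

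**Figure D5:**
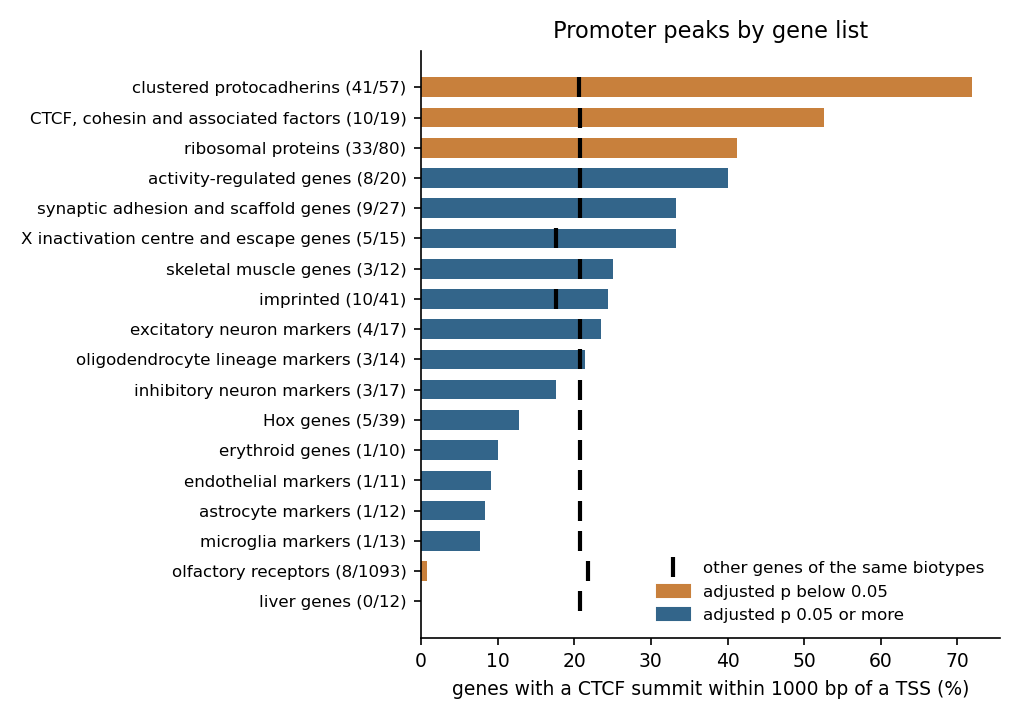
Share of genes in each list with a CTCF summit within 1000 bp of a TSS (horizontal axis, percent), with the counts beside each list name and a tick for all other genes of the same biotypes. Clustered protocadherins (71.9%) lie farthest above their tick and olfactory receptors (0.732%) farthest below theirs.

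When the whole gene and 10 kb upstream were searched, 61.3% of protein-coding genes (13454 of 21938) and 39.4% of lncRNA genes (3996 of 10155) had a summit. Imprinted genes were among 6 lists that passed the length-matched permutation test. A summit was present at 38 of 41 (92.7%), against 26.2 in length-matched random lists (adjusted permutation p = 0.0012). The strongest lay at Inpp5f (chromosome 7, 128690185 to 128690626), H13, Kcnk9, Trappc9, Cdkn1c, which encodes a cell cycle inhibitor, and Plagl1, all at or above the 95.4 percentile of conservative peaks. Kcnq1ot1, Mirg and Ndn had none. H19, named here after its values were seen, had 4 summits between chromosome 7, 142580291 and 142582018, upstream of the gene, in the part of the locus that holds its imprinting control region. None of the 4 had a motif match at the threshold used.

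Of the other lists, 5 also passed this length-matched permutation test. Ribosomal protein genes had a summit in 59 of 80, against 31.0 in matched lists (adjusted permutation p = 0.0012), and olfactory receptors in 66 of 1093, against 476 (0.0012). Clustered protocadherins had one in 49 of 57, against 40.7 (0.026), where 16 distinct peaks were the strongest peak of these 49 overlapping genes. Hox genes had one in 26 of 39, against 17.3 (0.026), again with 16 distinct strongest peaks. Activity-regulated genes had one in 16 of 20, against 10.3 (0.034). The matched lists were drawn from all genes of like biotype and length, olfactory receptors among them. Against other protein-coding genes unmatched on length, Hox genes lay near the background, at 66.7% against 61.3% (adjusted Fisher's exact p = 0.62). Activity-regulated (0.22) and ribosomal protein genes (0.065) did not pass that test either, while synaptic genes did (0.0022). Imprinted genes, clustered protocadherins and olfactory receptors passed both tests. For imprinted genes the background was protein-coding and lncRNA genes together, of which 54.3% had a summit. Without any upstream reach the calls for imprinted genes (adjusted permutation p = 0.54), protocadherins (1), Hox genes (1) and ribosomal proteins (0.16) were lost, and with 50 kb that for imprinted genes (0.11). The Hox call was lost in either pool's own list (0.07 and 0.33), and that of activity-regulated genes in the optimal list (0.063) and pool J's list (0.071).

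The other 12 lists did not pass the length-matched test. X inactivation and escape genes had a summit in 13 of 15, against 9.94 in matched lists (adjusted permutation p = 0.24). Those lists were not matched on chromosome, although X had fewer peaks per Mb than every autosome. The strongest peak of this list was at Kdm6a, a histone demethylase gene that escapes inactivation, then at Eif2s3x. A single peak at chromosome X, 103484033 to 103484410, just upstream of Xist, the RNA that silences the inactive X, was the strongest of Xist, Tsix and Jpx alike, and Ftx followed. Cdx4 and Ddx3x had none. Synaptic genes had a summit in 25 of 27, against 22.9 in matched lists (0.46). The cell type lists ranged from 5 of 11 endothelial markers (0.18) to 12 of 14 oligodendrocyte lineage markers (0.18). Skeletal muscle genes had one in 10 of 12 (0.13) and passed in pool I's own list (adjusted permutation p = 0.041).

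The seventh comparison looked for crowded sites. The densest 100 kb window in the genome was the Firre locus on X, although X had fewer sites per Mb than every autosome. Chromosome X, 50550001 to 50650000, held 29 summits, against a median of 10 and a maximum of 13 in the densest window of 100 random sets (one-sided permutation p = 0.0099, the smallest they can give). No protein-coding gene lies in the window, and its nearest are Olfr1324, Stk26 and Frmd7. Firre, a lncRNA gene built of repeated segments, spans 50555744 to 50635321 and held 27 of the summits, 25 of them without a motif match at the threshold used. The next window, on chromosome 10 from 79700001, held 19 summits near Polrmt, Fgf22 and Rnf126. The others held 15 to 18. They lay near Copz1, Gpr84 and Zfp385a and near Prph, Tuba1c and Troap on chromosome 15, near Thra, Nr1d1 and Med24 on chromosome 11, and near Sfxn3, Pdzd7 and Lzts2 on chromosome 19. The remaining 4 lay near Tmem189, Ube2v1 and Cebpb on chromosome 2, near Fbxo6, Fbxo44 and Mad2l2 and near Espn, Hes2 and Acot7 on chromosome 4, and near Gng8, Ptgir and Dact3 on chromosome 7. In pool I's own list the chromosome 15 window from 103250001 was listed first, with 29 summits.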

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

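The tests of a region filter and of a difference between the pools as the whole cause were chosen after the result was seen, as was the decision to set aside the 2 tests on the pools' ranks.

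Of the strongest 1000 peaks in the ranked list of both pools, 227 (22.7%) were not in the conservative list, so the report's comparisons of that list with sequence, genes and regions leave them out. All of the 10 strongest were missing, 63% of the strongest 200 and 2.5% of the last 200 of the 1000. The strongest lay on chromosome 19, 59239405 to 59239924, between genes and 20432 bp from the TSS of Kcnk18, on chromosome 2, 32912378 to 32912857, in an intron of Fam129b, and on chromosome 5, 129724721 to 129725249, at the promoter of Nipsnap2. They held the motif in 87.2% of cases, against 83.6% of those kept. All but 2 overlapped a peak in pool I's own list, and all overlapped a peak in pool J's.

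A filter of regions by the authors is argued against, since 0% of the missing peaks had a score at or above the threshold (scores 68 to 537), and so is a difference between the pools as the whole cause, since the list of pooled reads, whose inputs are parts of the same reads, lacked 25.9% of its own strongest 1000. The pools' ranks differed more at missing than at kept peaks, 3.06-fold in median size on the log2 scale and 3.41-fold within bins of 100 ranks, and with 48.9% of the missing peaks also absent from the list of pooled reads this met the conditions written beforehand for a difference between the pools. Those tests were then set aside as undecided, because the IDR is computed from the same ranks (Spearman's rho with the score -0.740 over 1000 peaks, judged by a limit chosen once the values were known), so a difference between the pools stays open for part of the loss. The treatment of extreme ranks by the IDR model is a further candidate and stays open too. The share missing was 25.2 times higher in the strongest 200 than in the last 200, which met the condition written beforehand. That ratio restates the pattern, so it cannot tell this candidate from other causes that act on the highest ranks. The pools' own lists lacked only 0.3% and 0% of their strongest 1000. No biological explanation was tested.

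The ranked list of both pools also held 65 peaks on scaffolds outside chromosomes 1 to 19, X and Y, and 25 on the mitochondrial chromosome, which drew attention because they lie outside every thresholded list and entered the report only through the signal correlation over all ranked peaks.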

How the results depend on the processing

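Of the settings here, only the list of strongest peaks by signal value and the length outside repeats were chosen after the data were seen. The 2 pool lists, the depth of which is unknown, limit what leaving out a pool can show. No paired analysis was possible because the lists merge both libraries of a pool, so no value carries a technical replicate number.

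The counts of peaks, the consistency ratios, the sharing between pools, the motif share, the promoter and intergenic shares and the summit count of the densest window kept their direction and their side of the threshold under every alternative run. Sharing ranged from 52.0 to 88.8% of pool I and from 80.2 to 99.1% of pool J peaks, and the motif share from 13.3 to 74.3%. Where values moved, the cause was not tested.

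With all ranked peaks the correlations of signal fell to 0.875 (Spearman) and 0.916 (Pearson). With the 0.1% motif threshold the convergent share was 24.7%, on the other side of random. The density of X relative to autosomes was 0.514 when all peaks were divided by the length outside repeats. It was 0.367 to 0.395 with a pool left out.

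The number of lists past the threshold at promoters, 4 as reported, was 7 with a 5000 bp window and 3 to 7 with a pool left out. In whole genes, 6 as reported, it was 2 without upstream reach.

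Leaving out replicate 1 leaves pool J's list, and leaving out replicate 2 leaves pool I's. Lists that did not pass the threshold in the test named changed sides as follows, at promoters of the share in other genes and in whole genes of the mean of length-matched lists. Values are shares of genes with a peak, and none of them passed the threshold. At promoters with 5000 bp these were Hox 53.8%, inhibitory 41.2%, astrocyte 50% and erythroid 50%. With 500 bp they were excitatory 11.8%, oligodendrocyte 14.3% and muscle 8.33%. The optimal list gave excitatory 23.5%. With a pool left out the ranges were excitatory 23.5 to 41.2%, where only the lower value, from pool J's list, changed sides, oligodendrocyte 21.4 to 35.7% and muscle 25 to 33.3%. In whole genes, an IDR of 0.01 gave CTCF and cohesin 73.7% and excitatory 70.6%. Excitatory markers gave 76.5% in the optimal list and by signal value, 76.5 to 94.1% with a pool left out, 58.8% without upstream reach and 94.1% with 50 kb. Without upstream reach astrocyte gave 50% and microglia 30.8%, and with 50 kb inhibitory gave 76.5% and erythroid 90%.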

Other observations

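The gene families, the summits at Peg13, the ratio of the pools on X, the repeat shares and the tests of promoter motifs were chosen after the main results were seen, the last after the lower share at promoters was seen but before they were run.

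A further 20 gene families, picked by symbol, were compared with other protein-coding genes for promoter peaks. Of these, 3 passed the adjusted threshold, all with fewer promoter peaks than other genes. Vomeronasal receptors, which detect pheromones, had a promoter peak in 2 of 331 (0.604%; adjusted Fisher's exact p = 2.2e-29), keratins and keratin-associated genes in 3 of 113 (2.65%; 3.2e-07) and cytochrome P450 genes in 5 of 100 (0.00012). Against lists matched on length, these 3 also passed (adjusted permutation p = 0.0013 each). Both tests treat genes as independent, which genes side by side in a cluster are not. No family was higher past the adjusted threshold. Proteasome subunits came nearest, with 15 of 40 (37.5%; adjusted Fisher's exact p = 0.068), ahead of cadherins outside the clusters (13 of 35; 0.074). Potassium channels (21 of 94) and zinc finger genes named Zfp (90 of 394) lay near the 20.8% of all protein-coding genes.

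At Peg13 the conservative list held 3 summits, at chromosome 15, 72809205, 72810129 and 72810341, and the last 2 had a motif on the reverse strand.

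Pool I's list held more peaks than pool J's, and 30295 of them met no pool J peak. Background called as peaks is argued against as the whole cause, since these peaks held the motif 47.5 times as often as their flanks. The threshold in pool J could account for part of them, as 48.3% overlapped a peak of pool J's ranked list (2.56% under shifts), below the 50% set beforehand for the whole. A difference in depth was not tested, as no depth is in the lists, and a difference between the mice of the pools stays open and untested.

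Promoter peaks held the motif less often than other peaks, at 35.7% of 2395 against 69.4% of 18466 on the even-numbered autosomes and X. Weaker peaks at promoters are argued against, since other peaks drawn to the same deciles of signal stayed 32.6 percentage points higher. Whether summits lay farther from the motif at promoters could not be decided. In windows of 200 bp the difference above flanks was 21.5 points. The threshold there was stricter, so the shares fell to 15.5% at promoters and 37.1% elsewhere, and distant matches of ordinary score could be missed. Copies below the score threshold are argued against as the whole cause, with 24.1 points above flanks at a threshold that 5% of flanks passed. The shares then rose to 66.6% at promoters and 90.2% elsewhere, so such copies could account for part. What lowers the share stays open. No biological explanation was tested.

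The median log2 ratio of pool I to pool J signal was 1.19 on X, above the 1.04 to 1.13 of the autosomes, and at matched signal X exceeded other chromosomes by 0.03, the highest of 20 chromosomes. With unit and read depth unknown, these ratios are not read as differences in binding.

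Repeats made up 46.8% of non-N sequence on X, against an autosome median of 33.4% and maximum of 35.8%.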
